A study of Caenorhabditis elegans with 8 samples.

How the data were processed

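Whole *C. elegans* of strain Bristol N2 were sampled at 4 stages. Per the labels, worms were synchronised with hypochlorite, grown in liquid culture at 20 °C, and taken as mixed-stage embryos, L1-L2 larvae, L3-L4 larvae and young adults. Larval samples were pools of intermolt and molting animals in volumes of 5, 5 and 2. Total RNA, and RNA immunoprecipitated with the J2 antibody against dsRNA (dsRIP), were fragmented and made into stranded libraries. Per the submitters' processing notes, reads were aligned with Novoalign to ce10 and handled with bedtools 2.19.0 and SAMtools 0.1.19. The title of 1 sample reads L4-L4, and its stage was taken from its characteristic, L3-L4.

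The deposited table gives FPKM, fragments scaled to feature length and library size, as computed by the authors, for 27050 features in 24 columns: 25509 genes and 1541 EERs. Of the EERs, 18 are not in the series-wide list of 1523. EERs were counted as features beside the genes, so a read may stand in both, and whether strand was used in counting is not stated. The deposited region lists give, for each EER, a position and a score, a whole number whose meaning the files do not state; it was used only to take the upper 50% of the regions in an alternative. Coordinates are ce10. Symbols and RNA classes came from a WBcel235 annotation joined by sequence name only, for 25092 genes, and 417 had no match. No position was taken from that annotation.

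Each column belongs to 1 of 8 samples, and 0 columns were left unmapped. The 3 numbered columns of a sample were averaged, since the labels define 1 sample per stage and molecule. The steps between FPKM values gave back whole reads: 99.9941% of values above 0 came out within 0.05 of a whole number, and 0 gene lengths stayed unsolved. Columns held 348064 to 914442 reads (median 527607). The 3 columns of a sample differed 5.91 to 13.0 times more than counting noise, as chi-square per degree of freedom over genes with at least 30 reads.

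The design written before the data were examined assumed normalised counts with a filter of 10. As the values are per kilobase, its rule for that case was used: FPKM of at least 1 in at least 2 of 8 samples. The dsRIP and total RNA samples were compared with limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with trend) on log2(FPKM + 1), with stage as a block. Genes and EER features were tested in the same fit, with Benjamini-Hochberg adjustment over all features and a threshold of 0.05. Lists were tested with camera at a preset correlation of 0.01 and again with the correlation estimated, and with fry. Of 22 lists, 20 were tested: the microRNA loci matched no tested gene, and the ADAR enzymes have only 2 members. The adjustment over the list alone was a second Benjamini-Hochberg step within a list. Shares of reads by RNA class were compared over the 4 stages with an exact sign-flip test.

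For the stages each level was compared with the mean of the other 3 stages, without a test, and genes at least 4-fold apart with an FPKM of at least 50 were counted. List medians were set against 10000 random lists drawn from 60 bins of expression. EER lists were compared with bedtools 2.31.1, counting an overlap of at least 1 bp on either strand. Gene spans in ce10 came from the table. The share of EERs in the outer 25% at each chromosome end was set against 100000 binomial draws at the share of tested genes there. The permutation of positions between whole clusters, planned beforehand, was not run. Where a molecule or stage had 0 reads for a feature, the fold was bounded with 3 reads over the group in place of 0. Where that floor turned the sign there was no bound, and the log2 difference counted as 0 in list medians. These bounds were added after the data were seen. Fitted folds of such features are no bounds.

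Features named in the text follow a rule fixed beforehand: the 10 genes and 5 EERs each way with the largest change among those past the threshold and with the same sign at all stages, the 5 largest stage differences, the 5 longest EERs, and the 2 to 4 most abundant members of each list. The rule also names both ADAR genes, dcr-1, rde-1, rde-4 and rrf-3. For dsRIP the number was narrowed to 2 for some lists after values that turned direction were seen. Features with at least 30 reads in all 8 samples, or at least 100 reads for stages, and all fits over single columns were chosen after the data were seen.

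The alternatives fixed beforehand were a pseudocount of 0.5 or 5, no filter or a filter of 50, equal medians, quantile normalisation, no stage block, no trend, 1 stage pair left out, an estimated correlation, an FPKM minimum of 10, an overlap of at least 50% of each region, the upper 50% by score, the outer 33.3% of each chromosome end, and EERs merged within 10 kb. Added later were filters of 10 or 30 reads, FPKM of the summed reads, fits over 24 columns, voom, same-strand overlap, young adults without column 3, and, for the test of the dsRIP ratio between stages over columns, 3 reads in place of 0 and no pairing by number. The fit was tested on simulated data with 20562 features. It recovered 16 of 100 features changed 2-fold and 71 of 100 changed 4-fold, with 1 false call. The fit over 24 columns recovered 67 and 93, with 5 false calls. Changes were planted only in well-covered features, with the same fold at every stage and a dispersion of 0.0324 between columns. Variation of the dsRIP ratio between stages was not simulated, so these figures do not give the power or the false calls in the real data. Tables and figures were made with Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9. Strand-separate signal tracks named in the labels were not used here.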

Results

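The series measured RNA from whole wild-type *C. elegans* (Bristol N2) at 4 stages: embryos, L1-L2 larvae, L3-L4 larvae and young adults. At each stage total RNA was sequenced beside dsRIP RNA, the RNA pulled down with an antibody against double-stranded RNA (dsRNA). The labels define 8 samples, 1 per stage and molecule. The deposited table holds 3 numbered columns per sample, and the labels do not say whether the 3 are separate cultures or technical repeats of 1 culture. In embryos and larvae, deviations of same-numbered total RNA and dsRIP columns correlated at 0.28 to 0.55, and those of other numbers at -0.09 at most. For these stages this argues against repeated sequencing of 1 library. Separate cultures and separate preparations of 1 culture cannot be told apart. Values below are the mean of the 3 columns with their SD, and each sample counts as 1 replicate. The table lists 25509 genes and 1541 editing-enriched regions (EERs). An EER is a stretch of genome where the study found clustered A-to-I editing, the mark that ADAR enzymes leave on dsRNA. The reads behind the values summed to 2007427, 1992079, 2264595 and 2002283 for total RNA of embryos, L1-L2 larvae, L3-L4 larvae and young adults, and to 1211042, 1263173, 1751557 and 1261847 for dsRIP in the same order. Over the 8 samples the median tested gene had 122 reads and the median tested EER 33. Coordinates are in ce10, counted from 1, and spans include introns, so whether an EER lies in an exon, intron or UTR is not known here. The p-values rest on the spread between numbered columns or between stages, and where they rest on columns that spread may be technical. Intervals and floors cover counting error only.

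The comparison of dsRIP with total RNA asks which transcripts the dsRNA antibody recovers. Small nuclear RNAs, which build the spliceosome, and small nucleolar RNAs (snoRNAs), which guide rRNA modification, made up most of the strongest losses. The snoRNA K12D12.7 (chromosome II, 11876493-11876553) had an FPKM of 31086 ± 7649 in total RNA of embryos and 1007 ± 331 in dsRIP, a log2 ratio of -4.80 ± 0.14 (SE, adjusted p = 0.00367) over the 4 stages. Its neighbours K12D12.6 and K12D12.8 gave -4.81 and -4.59, and reads shared within this cluster were not separated. The snRNAs C53D6.12, F32B5.9 and ZK897.3 fell by 5.63 ± 0.69, 4.50 ± 0.40 and 4.47 ± 0.51 on the log2 scale (adjusted p = 0.0268, 0.0161 and 0.0247). The splice-leader RNA gene sls-2.8 had 23 reads in total RNA and 0 in dsRIP, and the non-coding RNA F36H12.65 had 30 and 0, which makes them at least 5.09-fold and 6.64-fold lower against a floor of 3 reads over the 4 dsRIP samples. T08G5.18 and the snoRNA C50C3.14 fell by 5.26 and 4.73.

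A smaller group rose in dsRIP. Among well-covered genes this held for the snoRNAs Y37E3.20 and F54E7.11 and for mitochondrial transcripts. Y37E3.20 (chromosome I, 2085040-2085158) went from 122 ± 88.7 to 980.1 ± 404 FPKM in embryos, with a log2 ratio of 2.54 ± 0.18 (adjusted p = 0.0113), and F54E7.11 gave 2.38 ± 0.17 (adjusted p = 0.0112). The mitochondrial gene MTCE.12, whose span lies within that of ND1, rose by 2.36 ± 0.24 (adjusted p = 0.0206). The other genes with the largest ratios were covered by few reads: the piRNA locus 21ur-9213 (5.10, 10 reads in all), M70.6 (3.86, 8 reads), Y39G8C.10 (3.58, 17 reads), Y87G2A.22 (2.75, 15 reads) and ZC412.13 (2.34, 15 reads). The overlapping entries Y51H7C.16 and Y51H7C.17 had 0 reads in total RNA and 5 in dsRIP, at least 2.51-fold more. Genes with at least 30 reads in all 8 samples, a selection made after the values were seen, added the mitochondrial genes ND1 (1.38 ± 0.15) and MTCE.35 (1.32 ± 0.11), the ribosomal protein gene rpl-23 (1.07 ± 0.10) and aps-3 (1.11 ± 0.10), which encodes a subunit of the AP-3 vesicle adaptor. On the lower side it added sup-39 and sup-6, snRNA-class genes that fell by 4.04 ± 0.53 and 3.43 ± 0.50, and the snoRNAs F25H2.14 and Y43F4B.12 (-4.26 and -3.50).

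Of 19091 genes tested with limma, 144 were higher and 438 lower in dsRIP, all 582 in the same direction at all 4 stages. The median gene had a log2 ratio of -0.12. Setting the median of all genes equal in every sample moved it to 0.04 and gave 409 higher and 291 lower, so the balance of higher and lower genes depends on the scaling. Without the stage block, 2 genes were higher and 10 lower, and without any 1 of the 4 stage pairs none passed, when 2635 to 3101 genes still had an unadjusted p under 0.05.

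By class of RNA, snRNAs had the largest fold loss in their share of reads in dsRIP. They took 1.31% ± 0.144 of reads in embryo total RNA and 0.421% ± 0.284 in embryo dsRIP, and 1.73% ± 0.547 against 0.118% ± 0.00145 in young adults. The mean fold over the 4 stages was 0.107 for snRNAs, 0.471 for snoRNAs, 0.487 for other non-coding RNAs, 0.533 for tRNAs and 0.619 for lincRNAs. EER features gained (2.36-fold), as did rRNA (1.92-fold), mitochondrial protein-coding genes (1.82-fold) and piRNA loci (1.12-fold), while nuclear protein-coding genes stayed at 0.991-fold. These 9 classes apart from nuclear protein-coding genes each moved in 1 direction at all 4 stages, for which the exact two-sided sign-flip p is 0.125, the smallest that 4 pairs can give. Gene by gene, 20 of 68 snRNAs and 25 of 135 snoRNAs were lower, 0 and 4 higher, with median log2 ratios of -1.54 and -0.62. Among 121 tRNAs 1 was higher and 3 lower (median -0.95), among 1064 piRNA loci 5 and 1 (0.17), and among 15386 nuclear protein-coding genes 116 and 360 (-0.14). The non-coding RNA class lost share but had a median of 0.08, with 10 of 1418 higher and 19 lower. For lincRNAs the median was only -0.08, with 0 of 16 higher and 1 lower. The shares of the small classes rest on few reads, 64 to 526 per sample for tRNAs and 76 to 3574 for lincRNAs.

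Among the gene lists fixed before the data were examined, ribosomal proteins and mitochondrially encoded genes had members higher and none lower in dsRIP over the 8 samples. Of 78 cytosolic ribosomal protein genes, which encode the protein part of the ribosome, 18 were higher and 0 lower over all genes tested, and 42 and 0 adjusted over the list alone (median log2 ratio 0.31, camera adjusted p = 2.61e-20, but 0.353 with the correlation estimated). Over the 24 columns 50 were higher and 1 lower. Random lists of matched expression were also above 0, with medians of 0.28, 0.16, 0.03 and 0.07 along the stages against 0.48, 0.41, 0.21 and 0.24. Their most abundant members were rpl-41.2 (0.68 ± 0.17, adjusted p = 0.0928) and rps-9 (0.63 ± 0.14, adjusted p = 0.0779). Of 11 mitochondrially encoded genes, which serve respiration, 6 were higher and 0 lower, and 7 and 0 adjusted over the list alone (median 0.97, camera adjusted p = 1.43e-06, but 0.353 with the correlation estimated). MTCE.25 gave 0.93 (adjusted p = 0.0492), MTCE.26, whose span overlaps it, 0.97 (adjusted p = 0.058), and COX3 -0.25, which turned to 0.04 under quantile normalisation.

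The ADAR substrates named in earlier work had median ratios of 0.66, 0.58, 0.09 and -0.04 along the 4 stages, a difference that was not tested as a list. Their column pairs overlapped between stages. They ran from 0.46 to 0.74 in embryos, 0.31 to 0.81 in L1-L2 larvae, 0.02 to 0.50 in L3-L4 larvae and -0.18 to 0.38 in young adults. Over the 4 stages 2 of 7 substrates were higher and 1 lower, and 3 and 1 adjusted over the list alone (camera adjusted p = 0.076). The lectin gene clec-41 rose by 0.88 ± 0.07 (adjusted p = 0.0148) and the aldehyde dehydrogenase gene alh-7 by 0.79 ± 0.09 (adjusted p = 0.0254). The non-coding RNA rncs-1, a Dicer-resistant dsRNA, went from 206 ± 39.5 to 748 ± 103 FPKM in embryos (log2 ratio over all stages 1.16 ± 0.27, adjusted p = 0.0837). The laminin gene lam-2 gave 0.10, and the substrate that was lower was the syntaxin gene unc-64. Neither ADAR gene passed over all genes tested: adr-2, the editing enzyme, gave -0.64 ± 0.14 (adjusted p = 0.0808; lower when adjusted over the list alone) and adr-1 gave -0.09, which became 0.07 with the medians set equal.

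The 40 genes of RNAi and dsRNA machinery were lower as a list (median -0.22, camera adjusted p = 0.0248, but 0.353 with the correlation estimated), with 8 members above 0 and 0 past the threshold in limma, also adjusted over the list alone, though 5 were lower over the 24 columns. The Dicer gene dcr-1 gave -0.27 (adjusted p = 0.193), the Argonaute gene rde-1 -0.63 (adjusted p = 0.0628), the dsRNA-binding gene rde-4 -0.41 and the RNA polymerase gene rrf-3 -0.17. Among the most abundant members, rde-12 gave -0.24, nrde-2 -0.28 and csr-1 0.20. This call was lost with the medians set equal (adjusted p = 0.19) and without the stage block (adjusted p = 0.266). Cuticle collagens were higher as a list (median 0.12, camera adjusted p = 0.000433, but 0.353 with the correlation estimated), with 0 of 148 past the threshold in limma and 2 over the 24 columns, as col-160 (0.15) and col-10 (0.33) show. Body muscle genes were higher (median 0.10, camera adjusted p = 0.0248, but 0.353 with the correlation estimated), with pat-10, a troponin C, up by 0.62 ± 0.08 (adjusted p = 0.0314), 1 of 13 genes lower, and 4 higher and 1 lower adjusted over the list alone. That call was lost without the L3-L4 pair (adjusted p = 0.0609) and without the stage block (adjusted p = 0.621), as was that of the collagens without the block (adjusted p = 0.283). With an estimated correlation none of the 6 list calls held, EER features among them (adjusted p = 0.113).

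The other lists did not pass camera. Histones had a median of 0.10 with 1 of 50 lower (0 adjusted over the list alone, adjusted p = 0.216), neurons -0.19 with 1 of 14 lower (0 and 2 adjusted over the list alone, adjusted p = 0.321), and ribosomal RNA 0.02 with 1 of 8 lower (also adjusted over the list alone, adjusted p = 0.637), or 0.17 with the member at 0 reads set to its floor. Over the 24 columns 2 rRNA genes were higher and 0 lower, against the direction of that call, 2 histones were higher and 2 lower, and 1 neuronal gene was higher and 2 lower. The abundant rRNA gene rrn-2.1 gave 1.23 ± 1.02. None passed over all genes in limma among maternal and germline genes (25, median -0.06, adjusted p = 0.521), zygotic regulators (16, -0.11, adjusted p = 0.992), vitellogenins (6, 0.11, adjusted p = 0.453), sperm genes (15, 0.08, adjusted p = 0.637), major sperm proteins (30, 0.14, adjusted p = 0.148), moulting genes (18, -0.20, adjusted p = 0.148), heterochronic genes (8, -0.09, adjusted p = 0.761), intestine (11, -0.08, adjusted p = 0.969) and the intracellular pathogen response (10, -0.39, adjusted p = 0.172). Adjusted over the list alone, 2 moulting genes were higher and 4 lower, and 1 heterochronic gene was lower. Over the 24 columns 1 germline, 2 moulting, 1 heterochronic and 1 intestinal gene were lower, and 1 moulting and 2 intestinal genes higher. The intestine list is positive in camera, which compares it with other genes, and negative in its median and in fry. Of 878 genes whose span overlaps an EER, 20 were higher and 24 lower, and 23 and 27 adjusted over the list alone (median -0.05, camera adjusted p = 0.917), a list the study's own regions define. Among them the initiation factor gene eif-2alpha rose from 190.1 ± 21.5 to 445 ± 24.98 FPKM in embryos (over all stages, adjusted p = 0.0223), the galectin gene lec-1 gave 0.32, and the snRNA F42C5.12 fell by 2.54 ± 0.24 (adjusted p = 0.0182).

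**Figure D1:**
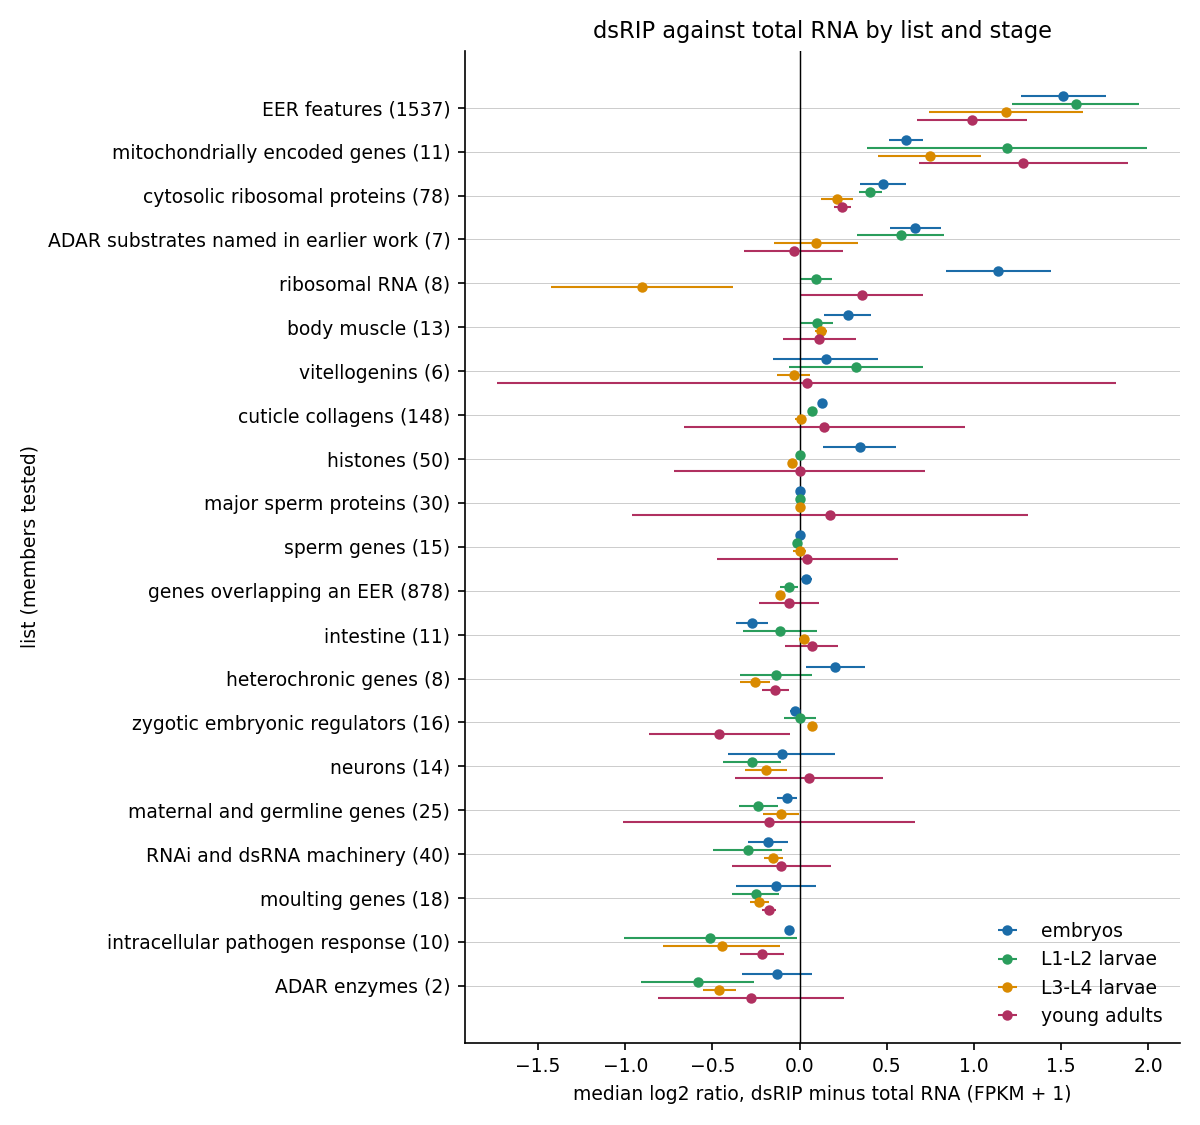
Median log2 ratio of dsRIP to total RNA, on FPKM + 1, for each of 21 lists at each of 4 stages. Points are the medians from column means, bars the SD of the medians of the 3 same-numbered column pairs, and numbers in parentheses the members tested. The pair medians need not centre on the points. EER features lie between 0.99 and 1.58, above nearly all other lists, and ribosomal proteins between 0.21 and 0.48.

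EER features, counted as features of their own, had ratios above 0 for 1446 of 1537 members. The largest well-covered ratio belonged to EA6_EER1475- (chromosome V, 19926774-19927823, no gene span), at 30.1 ± 2.41 FPKM in embryo total RNA and 129 ± 33.9 in embryo dsRIP, a log2 ratio of 2.18 ± 0.08 over the stages (adjusted p = 0.00474). EA6_EER375+ (chromosome I, 12748760-12749150) followed with 2.15 ± 0.12 (adjusted p = 0.00915), EA6_EER82- (chromosome I, 1346987-1347967) with 2.07, and EA6_EER891+ (chromosome III, 12622672-12623341) with 1.94 ± 0.08. EA6_EER53- (chromosome I, 1154606-1155338), next to the span of aps-3, gave 1.90 ± 0.15. These 5 were picked after the values were seen for at least 30 reads in all 8 samples, overlap no gene span and are in all 4 stage lists. The 5 largest ratios by the rule fixed beforehand had 0 reads in total RNA: EA6_EER668- (chromosome III, 1196647-1196698) had 21 reads in dsRIP, EA6_EER404+ 19, EA6_EER61+ within smg-2 12, EA6_EER60- within haf-6 11 and EA6_EER1060+ within Y71G10AR.4 9. Against a floor of 3 reads over the 4 total RNA samples they were at least 10.5, 9.54, 6.03, 5.52 and 4.52-fold higher.

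Of 1537 EERs tested, 291 were higher in dsRIP and 0 lower in limma over all features, with 975 at an unadjusted p under 0.05. Adjusted over the list alone, 808 were higher and 7 lower, and 6 were lower over the 24 columns and with voom. The list was chosen by the study on these samples, so its direction is not independent evidence (camera adjusted p = 1.05e-66, but 0.113 with the correlation estimated). The median log2 ratio was 1.37, and 1.36 with the 24 EERs that have a molecule at 0 reads set to their bound. By stage it was 1.51 in embryos, 1.58 in L1-L2 larvae, 1.18 in L3-L4 larvae and 0.99 in young adults, from the means of the columns. The medians of single column pairs had SDs of 0.24, 0.36, 0.44 and 0.31 in that order, but need not centre on these values. In L3-L4 larvae the pairs gave 0.33, 1.12 and 1.06, all below 1.18. The 3 column pairs of the young adults gave 0.62, 0.00 and 0.24 on their own, below the value from their means. The cause of this gap was not tested. Without the stage block 11 EERs passed, and without any 1 stage pair 0 did, when 703 to 902 had an unadjusted p under 0.05.

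The stage lists ask which edited dsRNAs occur when. Young adults had the fewest EERs: of the 1523 EERs of the whole series, 135 overlapped the young adult list, against 566 for embryos, 456 for L1-L2 larvae and 348 for L3-L4 larvae. The bases covered by the stage lists were 299620, 208734, 139303 and 50545 in stage order. Of all EERs (median 417 bp, 52 to 4690 bp), 85 overlapped a region in all 4 stage lists, 131 in 3, 184 in 2 and 404 in 1, while 719 overlapped none. Embryos had 242 EERs of their own, L1-L2 larvae 106, L3-L4 larvae 50 and young adults 6. The longest was EA6_EER124+ (chromosome I, 1568675-1573364) in src-1, a Src kinase gene, in all stage lists but that of L3-L4 larvae. EA6_EER972+ in Y38C1AA.1 (4237 bp), EA6_EER726- in daf-2 (3847 bp), the insulin receptor gene, and EA6_EER1433- in snx-6 (3827 bp), a sorting nexin gene, were in all lists but that of young adults. EA6_EER179+ in eif-2alpha (3755 bp), EA6_EER595- in alh-7 and E01G4.6 (3720 bp), EA6_EER612+ in lem-2 (3361 bp), a nuclear membrane protein gene, EA6_EER828- in Y56A3A.2 (3103 bp) and EA6_EER1059+ in hrpu-2 (2774 bp) were in all 4.

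No test was made on these numbers, with 1 list per stage. EER features took 1.09% ± 0.126 of reads in embryo total RNA, 0.670% ± 0.0470 in L1-L2 larvae, 0.586% ± 0.0630 in L3-L4 larvae and 0.574% ± 0.126 in young adults. In dsRIP the shares were 2.69% ± 0.0161, 1.88% ± 0.376, 1.26% ± 0.278 and 1.18% ± 0.331. With an overlap of at least 50% of each region, 39 EERs instead of 85 were in all 4 lists.

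**Figure D2:**
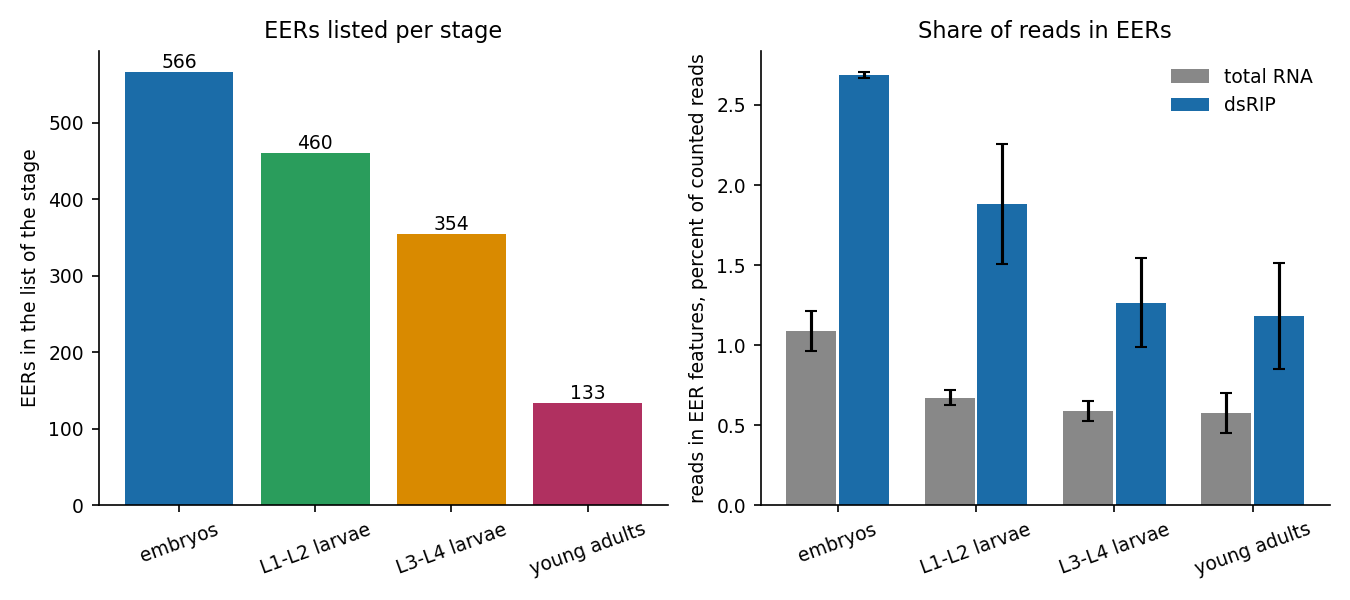
Left, number of EERs in each stage list, from 566 in embryos to 133 in young adults. Right, percent of counted reads in EER features at each stage for total RNA (grey) and dsRIP (blue), with the SD of the 3 columns as error bars; embryos hold the highest share in both molecules, 1.09% and 2.69%.

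The lists by molecule ask whether edited regions found in total RNA are also found in the pulldown. By an overlap of at least 1 bp, 458 of the 505 EERs of total RNA (90.7%) overlapped a region of the dsRIP list, but with an overlap of at least 50% of each region only 239 (47.3%) did. Of the 1523 EERs, 1137 overlapped the dsRIP list and 499 the total RNA list: 463 overlapped both lists, 674 the dsRIP list alone, 36 the total RNA list alone and 350 neither. The EERs in src-1, daf-2, snx-6, lem-2, eif-2alpha and alh-7 were in both. The total RNA regions were shorter, with a median of 245 bp against 401 bp. With the stricter overlap 223 of the 1523 EERs were in both lists.

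The position of EERs along chromosomes was compared with that of genes. EERs lay near the chromosome ends: 1260 of 1473 autosomal EERs (85.5%, exact binomial interval 83.6% to 87.3%) fell in the outer 25% at either end of their chromosome. Of 16309 tested autosomal genes 41.3% lie there (simulated binomial p = 1e-05, two-sided, the smallest that 100000 draws can give). The draws treat EERs as independent. Counted once per group of EERs within 10 kb, 546 of 739 (73.9%, the same p) fell in the outer 25%. Chromosome I held 443 EERs (29.1%, against 14.7% of tested genes) and chromosome III 322 (21.1% against 14.1%). Chromosome II held 191, IV 273 and V 244, and X only 50 (3.28%, interval 2.45% to 4.31%, against 14.5% of tested genes). The interval treats neighbouring EERs as independent, and counted once per group within 10 kb X held 42 of 781 (5.38%). Spans of protein-coding genes, such as daf-2 and src-1, overlapped 1143 EERs, and 324 overlapped no gene span. In all, 887 genes had an EER in their span, 815 of them protein-coding.

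**Figure D3:**
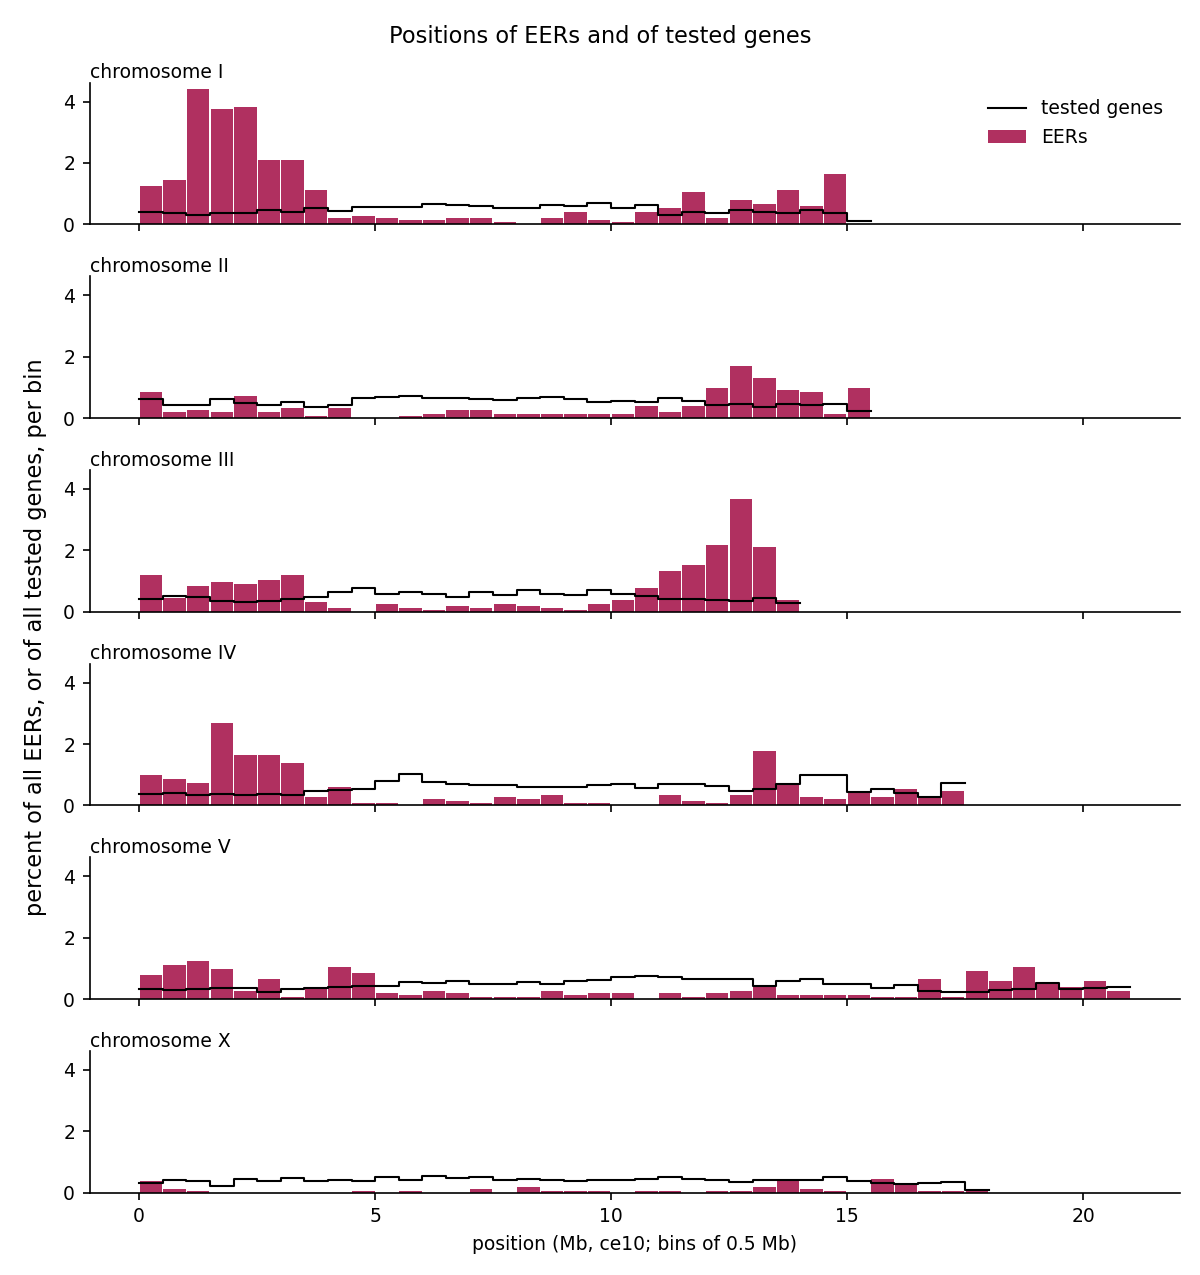
Position of the 1523 EERs along each chromosome in ce10. Bars are the percent of all EERs in each 0.5 Mb bin and the black line the percent of all tested genes; on the autosomes the bars crowd at the ends, with 85.5% of EERs in the outer 25% at either end.

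The stage comparison in total RNA asks how the transcriptome changed from embryo to adult. Young adults stood apart by reproductive genes. The 6 vitellogenins, yolk proteins made in the adult intestine, had a median log2 difference of 8.41 from the other stages, and vit-6 stood at 0.692 ± 0.898, 1.86 ± 1.65, 6.38 ± 3.86 and 1592 ± 1175 FPKM along the stages. Major sperm proteins had a median of 6.25 in young adults, with msp-33 listed at 0 in embryos and at 369.6 ± 245 in adults. Maternal and germline genes had medians of 0.94 in embryos, -2.63 in L1-L2 larvae, -1.65 in L3-L4 larvae and 2.92 in young adults, and spn-4, a maternal RNA-binding protein gene, stood at 155 ± 26.2, 4.61 ± 2.67, 12.5 ± 1.62 and 165 ± 115 FPKM. Adult cuticle collagens were the single genes with the largest adult difference: col-106 reached 4906 ± 1516 FPKM and col-122 2304 ± 394, where col-122 was listed at 0 in embryos.

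Embryos were marked by histones (median 2.77) and zygotic regulators (2.55). The histone gene his-64 stood at 17354 ± 10506 FPKM in embryos and 861 ± 179 in L1-L2 larvae, and elt-1, an epidermal GATA factor gene, at 50.7 ± 7.84 and 13.1 ± 3.06. Among the single genes with the largest embryo difference were dpy-17, a collagen gene, at 1831 ± 399 FPKM against 22.6 ± 9.69 in L1-L2 larvae and 9.29 ± 4.45 in adults, and ttr-50, of the transthyretin-related family, at 1788 ± 276 against 13.9 ± 4.14, while the collagens as a list were low in embryos (median -2.91). Moulting genes, which renew the cuticle, had medians of 1.46 in embryos, -0.01 in L1-L2 larvae, 0.98 in L3-L4 larvae and -2.34 in adults, and noah-1 stood at 405 ± 34.4, 51.6 ± 41.4, 125 ± 62.4 and 7.71 ± 5.69. Ribosomal proteins had a median of -1.91 in embryos and of 0.73, 0.90 and 0.27 later. The ADAR genes were highest in embryos, adr-1 with 63.7 ± 12.8, 23.7 ± 3.32, 29.8 ± 3.97 and 26.98 ± 0.433 FPKM and adr-2 with 52.2 ± 2.23, 24.7 ± 4.01, 20.9 ± 3.19 and 33.6 ± 18.8.

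Markers of somatic tissue were high in larvae, those of neurons mainly in L1-L2 larvae. Neuronal genes had a median of 2.14 in L1-L2 larvae, 0.27 in L3-L4 larvae and -1.18 in adults, and egl-21, a neuropeptide-processing enzyme gene, stood at 206 ± 31.4 FPKM in L1-L2 larvae and 11.8 ± 5.86 in embryos. Body muscle, intestine and collagens had medians of 1.11, 1.03 and 0.63 in L1-L2 larvae, of 0.79, 1.17 and 0.97 in L3-L4 larvae and of -1.67, -2.24 and -2.91 in embryos. The myosin gene unc-54 stood at 117 ± 37.02 FPKM in embryos, 902 ± 124 in L1-L2 larvae and 927 ± 149 in L3-L4 larvae, and the aspartyl protease gene asp-1 at 134 ± 74.6, 1585 ± 739 and 1867 ± 1132. In L3-L4 larvae the cuticle collagen gene bli-2 (181 ± 49.7 FPKM, listed at 0 in L1-L2 larvae) and lep-5, a long non-coding RNA of developmental timing (2629 ± 466 against 40.2 ± 35.2 in L1-L2 larvae), had the largest well-covered differences. The early timing gene lin-14 stood at 108 ± 8.29, 93.2 ± 20.0, 38.9 ± 14.3 and 17.7 ± 6.00 along the stages. RNAi machinery had medians of 0.52, -0.69, -0.28 and 0.68, with csr-1, a germline Argonaute gene, at 9.99 ± 1.99, 15.3 ± 1.32, 66.0 ± 23.7 and 158 ± 62.5 FPKM.

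No test over samples was made within a molecule, with 1 sample per stage in each, and each list was set against 10000 random lists of matched expression. The medians for vitellogenins, major sperm proteins and germline genes in adults, histones and zygotic regulators in embryos, and neurons, muscle and collagens in L1-L2 larvae lay at the 100th percentile. In a limma fit over columns, added after the data were seen, all 6 vitellogenins, 28 of 30 major sperm proteins and 22 of 25 germline genes were higher in adults, 27 of 50 histones and 14 of 16 zygotic regulators in embryos, and 11 of 14 neuronal and 9 of 13 muscle genes in L1-L2 larvae. Collagens in L1-L2 larvae went both ways, with 21 higher and 28 lower of 148, although their median was above 0. In L3-L4 larvae 1 of 14 neuronal, 5 of 13 muscle and 4 of 11 intestinal genes were higher and none lower, and 49 collagens were higher and 18 lower. In embryos 73 of 78 ribosomal protein genes and 85 of 148 collagens were lower, and 1 and 18 higher. For the remaining lists the highest stage median of total RNA was 1.70 for sperm genes (young adults, 5 of 15 higher and 0 lower), 0.88 for heterochronic genes (L3-L4 larvae), 0.85 for the intracellular pathogen response (L1-L2 larvae), 0.80 for mitochondrial genes (L3-L4 larvae) and 0.69 for rRNA (L3-L4 larvae). Of the 8 heterochronic genes 1 was higher and 2 lower in L3-L4 larvae, but 4 higher and 0 lower in L1-L2 larvae. Of the 10 pathogen response genes 2 were higher and 0 lower in L1-L2 larvae. No mitochondrial or rRNA gene was called in L3-L4 larvae, so those medians do not establish the stage of highest level. At least 4-fold above the mean of the other stages, with an FPKM of at least 50, were 708 genes in embryos, 317 in L1-L2 larvae, 224 in L3-L4 larvae and 375 in young adults, and 854, 384, 352 and 388 were 4-fold below. The rule fixed beforehand also picked piRNA loci with few reads, such as 21ur-3734 and 21ur-14414, whose 34 and 29 reads all came from embryos, and EA6_EER564- (chromosome II, 12755776-12755848), at 554 ± 211 FPKM in embryo total RNA. Some medians rest on members with no read at a stage: with these at their bound, major sperm proteins gave -3.46 instead of -2.95 in embryos, and sperm genes -0.68 instead of -1.18.

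**Figure D4:**
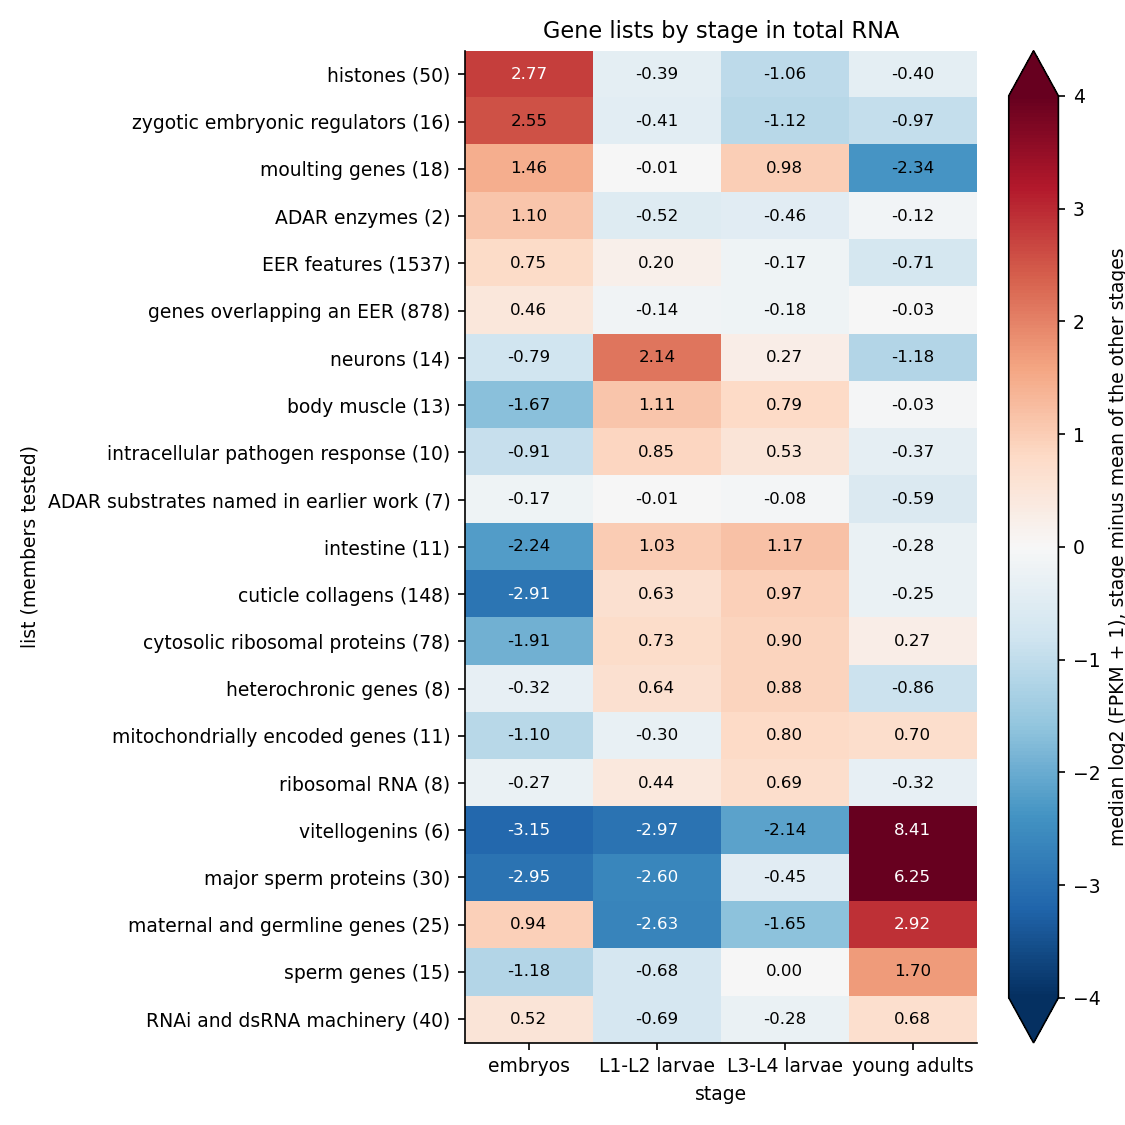
Heat map of list medians in total RNA, as the log2 level on FPKM + 1 of a stage minus the mean of the other stages, with colours from -4 to 4. Vitellogenins (8.41) and major sperm proteins (6.25) stand out in young adults and histones (2.77) in embryos.

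In dsRIP the same question gave much the same groups. The median differences were 8.31 for vitellogenins, 6.20 for major sperm proteins and 2.90 for germline genes in young adults, 2.83 for histones and 2.59 for zygotic regulators in embryos, and 1.81 for neurons in L1-L2 larvae. Collagens had a median of -2.57 in embryos. The collagen gene col-20 reached 1630.5 ± 142 FPKM and vit-6 1651 ± 1047 in young adult dsRIP, dpy-17 2689 ± 881 in embryos and bli-1, a collagen gene of the adult cuticle, 55.6 ± 23.998 in L3-L4 larvae. Mitochondrial genes had medians of -1.68 in embryos and 1.14 in young adults. In stage order 763, 392, 265 and 391 genes were at least 4-fold higher, and 881, 474, 477 and 544 lower.

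EER features differed between the stages in both molecules, with the highest levels in embryos. Their median against the other stages in total RNA was 0.75 in embryos, 0.20 in L1-L2 larvae, -0.17 in L3-L4 larvae and -0.71 in young adults, and in dsRIP 0.99, 0.61, -0.30 and -1.001. The EERs of the embryo list stood at 1.22 in embryo total RNA and 1.49 in dsRIP, both at the 100th percentile. Each stage list was called on the samples of its own stage, and calling needs reads there, so a high level at that stage is in part built into the lists. The series-wide list has a like limit: 566 of its 1523 EERs overlap the embryo list and 135 that of young adults. The high embryo level of all EER features may thus be built in to a degree. The EERs of the L1-L2 list stood at 0.36 and 0.86 in their own stage, those of the L3-L4 list at 0.07 and -0.04, and those of the young adult list at -0.02 and -0.17. In the fit over columns 247 of 1537 EERs were higher and 32 lower in embryo total RNA, and 12 higher and 110 lower in young adults. In dsRIP these were 334 and 47 in embryos and 17 and 262 in young adults. Of 19091 genes, 4371 were higher and 3526 lower in embryo total RNA, and 2282 and 2589 in young adults. In dsRIP these gene counts were 3940 and 3074 in embryos and 2509 and 1992 in young adults. Genes overlapping an EER had a median of 0.46 in embryos, where 346 of 878 were higher and 118 lower. The young adult medians rest in part on regions with no read: 489 of the 1537 had a group at 0 reads in the total RNA contrast. With these at their bound the median was 0.00, against -0.58 in dsRIP. Regions for which the floor gave no bound count as 0 in these medians, so 0.00 does not show equal levels. With the medians of all genes set equal, the L1-L2 median in total RNA became -0.07.

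Whether the dsRIP ratio itself differed between stages was tested over the 24 columns with limma. It did for 0 of 19091 genes and for 1 EER, EA6_EER1141- (chromosome IV, 7316740-7316798), which lies within the snRNA F42C5.12. Its FPKM in total RNA was 314 ± 122, 139 ± 92.1, 234 ± 103 and 222 ± 51.6 along the stages, and in dsRIP 176 ± 108, 147 ± 82.3, 69.8 ± 26.8 and 0. The result rests on the 0 reads in young adult dsRIP: with 3 reads there in place of 0 the adjusted p was 0.429, and no feature passed.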

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

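The test that picked out EA6_EER1141- and all tests on the explanations below were chosen only after the result was seen, except those on regions picked on the dsRIP libraries and on the abundance of the regions in young adults.

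EA6_EER1141- (chromosome IV, 7316740-7316798) stood out because its dsRIP ratio differed between the stages, as tested over the 24 columns with limma (adjusted p = 0.00523), the only feature for which it did before 0 reads were replaced by a floor. Its log2 ratio was -0.83 in embryos, 0.08 in L1-L2 larvae and -1.73 in L3-L4 larvae. In young adults, with 27 reads in total RNA and 0 in dsRIP, it was at least 5.67-fold lower (log2 ratio of -2.50 or less) against a floor of 3 reads. With that floor in place of 0 for every such feature the difference between stages was lost (adjusted p = 0.429), so the call rests on a sample without reads. The feature holds 145 reads in all. It lies within the snRNA F42C5.12, whose own FPKM in young adults was 1344 ± 784 in total RNA and 216 ± 19.5 in dsRIP. No biological explanation was tested.

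EER features were higher in dsRIP. The tables argue against few reads as the whole cause: the 142 EERs with a mean of at least 30 reads per sample had a median log2 ratio of 1.03 (quartiles 0.43 to 1.67), with 131 above 0, against -0.12 for genes. The median was 1.37 over all tested EERs and 0.77 for those with at least 30 reads in all 8 samples. Whether few reads add to the size thus stays open. Picking of the regions on the dsRIP libraries is also argued against as the whole cause, since the 499 EERs overlapping the total RNA list had a lowest stage median of 1.06 and a highest of 1.54. Their boundaries were drawn with dsRIP reads too, and 463 also overlap the dsRIP list, but the 135 that share at least 90% of each region with the total RNA list, a setting added later, gave 1.08 to 1.499. The 36 EERs of the total RNA list alone had a median of 0.32 (24 above 0). Absence from the dsRIP list itself selects for a low ratio, so this value cannot show whether such picking adds to the size. Binding of dsRNA by the antibody stays open as the biological explanation.

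Young adults had the fewest EERs. Their samples held 100.3% of the counted reads of the L1-L2 larvae, but 28.9% as many EERs. This argues only against fewer counted reads, which are those in listed genes and EERs. The number of reads on which the EERs were called is not given, so fewer reads at calling stay open as a cause. Lower adr-2 mRNA stays open, since adr-2 was 12.7 FPKM higher in young adults than in L3-L4 larvae with an SD between columns of 18.8. Lower abundance of the regions met its prediction: the 719 EERs of no stage list had a median of -0.60 in young adult total RNA. That is percentile 0.06 of matched random lists, whose medians were also below 0, from -0.64 to -0.14. As these EERs are in none of the stage lists, their level cannot show why the young adult list is the shortest. In addition, 299 of the 719 had a group at 0 reads, and the median was 0.00 with these at their bound. Regions for which the floor gave no bound count as 0 there, so 0.00 does not show equal levels. The cause may lie in the age of the animals, which no test here separates from the rest.

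The 3 young adult columns differed in reproductive genes: the vitellogenin median was 6.75, 9.43 and 10.19 in total RNA and 9.61, 9.52 and 8.996 in dsRIP. The medians spanned 3.44 within total RNA and 0.62 within dsRIP. No numbering changes a span within a molecule, so these spans cannot show whether numbers 1 and 3 were exchanged. Whether the numbers pair the columns of the molecules rightly stays open, with gaps of 2.24 and 0.58 exchanged and of 2.86 and 1.19 as numbered. More embryos inside the adults of total RNA column 3 fits for part of the genes: 62.1% of zygotic regulators and histones (9 of 16 and 32 of 50) were highest there, against 32.8% of all genes. Over total RNA columns 1, 2 and 3, medians were 6.95, 7.85 and 5.20 for major sperm proteins and 3.25, 2.77 and 1.14 for sperm genes. Those of collagens were 4.43, 4.55 and 2.47, and those of germline genes 5.48, 6.28 and 6.90. Whether embryos account for the low sperm and collagen values of column 3 was not tested. A difference in the age of the adults stays open, as untested.

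For the calls between dsRIP and total RNA, splits of the samples are too few for a share under 0.05: among the 8 splits that part all 4 pairs only 1, the real one, reached its 582 genes, with 0 as the highest other, and only 1 reached its 291 EERs, with 0 as the highest other.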

How the results depend on the processing

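All fits over columns and reads below, the one without young adult column 3, the overlap on the same strand, the filters of 10 and 30 reads and all settings of EA6_EER1141- were added after the data were seen; the other alternatives were fixed beforehand. Over all alternatives, 1475 values of named features kept their direction and side of the threshold, 316 lost a call and 30 turned direction, none of the latter past the threshold. Calls were gained in 6.13%, such as 26 with voom, 20 with columns crossed and 15 with at least 30 reads in all samples. Each of the 4 fits without a stage pair lost the calls of 53 named features, with too few pairs left; no stage block lost 39, no trend 27, no filter 9, a pseudocount of 0.5 lost 4 and quantile normalisation 5. Of the list tests 11 lost and 1 gained a call, the ADAR substrates without young adults (adjusted p = 0.0322), and 9 turned direction, none past the threshold. The median dsRIP ratio of all EERs stayed above 0 in every fit made, and the order of the stages by EER count under the 3 other ways of counting overlaps that were run. Features that a stricter filter removed have no value there. Where the construction shows no cause, the cause was not tested. The EERs had a median of 33 reads over the 8 samples and genes 122, and whether depth limits the EER calls was not tested.

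Filters moved counts in part by changing the features tested. For the pseudocount the cause was not tested. Without a filter 82 genes were higher and 237 lower, with 190 EERs higher. With a filter of 50, 286 genes were higher, and 81 EERs higher and 3 lower. With at least 10 reads in at least 2 samples 339 genes were higher and 1130 lower, and 4 EERs lower. With at least 30 reads in all 8 samples 457 and 840 genes and 40 and 1 EERs were higher and lower, with an EER median of 0.77. A pseudocount of 5 gave an EER median ratio of 0.81, and by stage 1.05 in embryos, 1.05 in L1-L2 larvae, 0.67 in L3-L4 larvae and 0.48 in young adults. EER levels were then 0.33 in embryo total RNA, 0.66 in embryo dsRIP and -0.34 in young adult total RNA, with 0.66 and 1.13 for the embryo list in embryo total RNA and dsRIP and 0.16 for the L1-L2 list in its own total RNA. Genes 4-fold higher in L3-L4 larvae were then 139 in total RNA and 172 in dsRIP, and those lower 184, 166 and 235 (total RNA) and 231, 193 and 315 (dsRIP) in L1-L2 larvae, L3-L4 larvae and young adults. Heterochronic genes in embryo total RNA turned to 0.084, egl-21 to 0.014 and gsp-3 to 0.0024.

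With an FPKM minimum of 10, genes 4-fold higher in total RNA were 2059, 1453, 753 and 1131 along the stages and those lower 1818, 811, 768 and 1062. In dsRIP they were 2247, 1627, 811 and 1256, and 1797, 1012, 899 and 1242.

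Scaling turned several small ratios. With the medians set equal 409 genes were higher and 291 lower, and egl-21 gave 0.15, gsp-3 0.018, lin-28 0.094, adr-1 0.070, wago-1 0.065 and act-5 0.080. The zygotic and heterochronic lists turned direction with an adjusted p = 0.949 each. EER levels gave -0.074 in L1-L2 total RNA and 0.88 in embryo dsRIP, the L1-L2 list 0.087 in its own total RNA, the embryo list 1.37 in embryo dsRIP, and genes overlapping an EER 0.041 in young adult dsRIP. Under quantile normalisation 248 genes were lower, and COX3 gave 0.041, act-5 0.080, egl-21 0.033, his-60 0.083 and his-64 0.20.

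Without trend 7 genes were higher and 30 lower, and 99 EERs higher. With FPKM of the summed reads 2 EERs were lower, and egl-21 gave 0.029. With voom 706 genes were higher and 1782 lower, and 889 EERs higher and 6 lower; egl-21 gave 0.12, gsp-3 0.28, wago-1 0.0053, col-167 -0.0028 and pal-1 -0.056. With an estimated correlation 0 lists passed.

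The stage block pairs the 2 samples of a stage. With no replicate block 2 genes were higher and 10 lower, 11 EERs were higher and 3 lists passed, and the intestine and rRNA lists turned direction (adjusted p = 0.965 and 0.751). The numbers of the columns do not pair all of them. Deviations of same-numbered columns correlated at 0.28 to 0.55 in embryos and larvae, but at -0.09, 0.47 and 0.01 in young adults, where columns 1 and 3 correlated best with another number. With the number as replicate block over 24 columns, 442 genes were higher and 1451 lower, and 574 EERs higher and 6 lower (egl-21 0.021). With young adult numbers 1 and 3 crossed, these were 489, 1563, 599 and 6 (egl-21 0.021). Without young adults they were 398, 1451, 530 and 3 (egl-21 0.0005, lin-28 0.079). The difference between stages in the dsRIP ratio of EA6_EER1141- was lost with 3 reads over a sample in place of 0 (adjusted p = 0.429, and 0.534 also with no replicate block), and kept with no replicate block alone (adjusted p = 0.000277).

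Without any 1 stage pair 0 genes were higher, 0 lower and 0 EERs higher, with 3 pairs left. Over these fits col-125 ranged from -0.015 to 0.13, egl-21 from -0.054 to 0.11, gsp-3 from -0.28 to 0.082, spe-4 from -0.027 to 0.35, vit-2 from -0.025 to 0.35, lin-28 from -0.12 to 0.062 and pal-1 from -0.066 to 0.18. The adjusted p ranged from 0.612 to 0.955 for genes overlapping an EER, from 0.648 to 0.944 for the intestine and from 0.578 to 0.944 for zygotic regulators.

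With an overlap of at least 50% of each region 39 EERs were in all 4 stage lists and 223 in both molecule lists. In the upper 50% by score 50 were in all 4 lists, 364 in none, 146 in the embryo list alone and 1 in the young adult list alone, with 291 in both molecule lists and 310 in the dsRIP list alone. The outer 33.3% at either end held 91.3% of EERs, and merging within 10 kb gave 73.9% in the outer 25%. Without young adult column 3 the EER median in young adult total RNA was -1.001.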

Other observations

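No test in this part was chosen after the result was seen; the limma fit was planned.

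Some genes of the lists were not described above. The cul-6 partner skr-3, of the intracellular pathogen response, stood at 34.9 ± 4.65, 84.7 ± 12.1, 79.0 ± 8.82 and 33.6 ± 11.5 FPKM in total RNA along the stages. The timing gene lin-41 stood at 3.22, 38.2, 24.6 and 51.3 FPKM, and lin-28 at 42.1, 37.1, 7.24 and 20.1. The collagen gene col-41 was seen in larvae, with 196 ± 169 FPKM in L1-L2 larvae, 94.4 ± 23.98 in L3-L4 larvae and 0.931 in young adults.

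The long non-coding RNA lep-5 was lower in dsRIP (log2 ratio -0.96, limma adjusted p = 0.0246). The rRNA share was 2.06% ± 1.04 in embryo total RNA and 3.04% ± 1.26 in dsRIP, and 7.54% ± 1.41 in dsRIP of L1-L2 larvae. EERs with at least 1 read numbered 1330, 1266, 1210 and 1035 in total RNA along the stages and 1440, 1452, 1415 and 1249 in dsRIP. Their median FPKM was 4.96, 3.67, 2.58 and 1.41 in total RNA and 16.3, 13.8, 8.25 and 4.85 in dsRIP.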
